A study of Homo sapiens with 14 samples.

How the data were processed

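The series held RNA sequencing (RNA) and ribosome profiling (Ribo) of the established human embryonic stem cell line HUES8 at 3 stages of pancreatic differentiation. These were definitive endoderm (DE), early pancreatic progenitors (PP1) and late pancreatic progenitors (PP2). Each assay had 2 DE, 2 PP1 and 3 PP2 libraries, 14 in all, and undifferentiated cells were not analysed here. A library was taken as the unit of replication. The sources used here did not say whether replicates came from separate differentiations.

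The authors deposited 1 table of raw counts per gene symbol and library, with 59050 gene symbols. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.18, reads were aligned to hg38 with Bowtie 1.2 and STAR 2.7.1a, and genes were counted with featureCounts 1.6.4. Which aligner step removed which reads, the strand setting, the annotation release and whether Ribo reads were counted over coding sequence or over whole exons were not given in the sources used here. All 14 count columns were matched to a sample, no 2 columns were identical, and no sample was left out.

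Total counts in the RNA libraries were 16942432 and 15107847 (DE), 16228393 and 20906646 (PP1), and 17515134, 18399517 and 21009065 (PP2). The Ribo libraries held 6108416 and 6090430 (DE), 5515246 and 4710335 (PP1), and 24186949, 7197910 and 10263760 (PP2). Counts in protein-coding genes ranged from 1409137 to 22127696 among the Ribo libraries.

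Each assay was fitted separately with its 3 stages together in edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr with default settings, library sizes were scaled by trimmed mean of M-values (TMM), and stages were compared with the quasi-likelihood F test after estimateDisp and glmQLFit. Translation efficiency (TE) here means the Ribo change minus the RNA change in log2 units. It was tested as an interaction in 1 quasi-likelihood fit of all 14 libraries with 6 groups, over genes passing the filter in each assay. P-values were adjusted over all tested genes of a comparison by the Benjamini-Hochberg (BH) method, and an adjusted p under 0.05 counted as passed. Fold changes are log2 with the standard error of the fit after the sign ±. Expression is given as CPM over TMM-scaled library sizes, as mean ± standard deviation over the libraries of a group. A gene with no count in a whole group was given only a bound, computed with 3 counts over that group, the upper 95% limit of a Poisson count of 0. A gene with 1 to 3 counts in the lower group was given the ratio of rates with its exact 95% counting interval. These counting limits cover the sampling of reads and not the spread between cultures.

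Lists of marker, pathway and structural genes, 35 in all with 750 members, were written from general knowledge before the data were examined. The fit settings and most alternatives were also set before the data were examined. Of the members, 741 were found in the table, 48 of them under an older symbol. Lists with at least 3 tested members were tested with camera (limma 3.58.1) with its preset correlation of 0.01 and BH adjustment over the lists of a comparison. The same test with a correlation estimated from the residuals was the stated alternative. With all libraries it gave the highest adjusted p of the alternatives tried for every list that passed. Beside each list the members that passed the genome-wide adjustment are counted, and then those that passed when adjusted over the list alone. List medians used fitted log2 fold changes. A second median with genes at the floor set to their bound, and those with 1 to 3 counts at their count ratio, is given where it differed. For TE it used the Ribo value minus the RNA value of such genes. Where each value was a bound, their difference is not itself a bound and depends on the depth of each assay.

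A gene was named if it belonged to a list, or if it ranked among the 8 highest or 8 lowest log2 fold changes that passed. For the RNA and Ribo rankings a gene also needed a mean of at least 10 CPM in the higher stage and no overlap between the libraries of the stages. For the TE rankings it needed a mean of at least 10 CPM over the 2 stages in each assay. Gene types came from RefSeq symbols, of which 18617 were protein-coding in the table. Small RNA genes, pseudogenes and antisense genes are uncertain, since their reads can come from overlapping or similar genes and the strand setting was not given.

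Alternatives were DESeq2 size factors, TMM without mitochondrially encoded and structural noncoding genes, no low-count filter, a filter at a mean of 50 counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, glmTreat at 2-fold, a fit of only the stages compared, RNA counts thinned to the Ribo depth, leaving out each library in turn, and fry for the lists. Per-library normalization by spike-in, reading-frame periodicity and read-length checks were not analysed here, because only gene counts were used. XIST, TSIX and Y-linked genes were not named, but they were not removed from the fits or from the counts of genes that passed.

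The pipeline was tested on simulated data in which 200 genes were changed by 2-fold (67 genes), 4-fold (67 genes) or 8-fold (66 genes) in counts drawn at the depth and spread of the real libraries. For RNA the share recovered at 2-fold, 4-fold and 8-fold was 5.97%, 50.7% and 81.8% for PP1 against DE, 8.96%, 62.7% and 86.4% for PP2 against PP1, and 2.99%, 68.7% and 87.9% for PP2 against DE. For Ribo it was 0%, 14.9% and 60.6% for PP1 against DE, 4.48%, 28.4% and 62.1% for PP2 against PP1, and 1.49%, 34.3% and 80.3% for PP2 against DE. For TE it was 0%, 13.4% and 47.0%, then 0%, 16.4% and 45.5%, then 0%, 25.4% and 63.6% in the same order of comparisons. Unchanged genes called numbered 8, 10 and 8 for RNA, 2, 4 and 3 for Ribo, and 2, 2 and 6 for TE. In a second simulation the glycolysis genes were raised 4-fold. Their list gave adjusted p = 1.3e-126 for RNA, 1.1e-57 for Ribo and 8.5e-31 for TE, and 1, 0 and 1 other lists passed. Most 2-fold changes were therefore missed by all 3 fits, and genes that did not pass cannot be read as unchanged. Each gene was drawn independently in these simulations, with no deviation shared by the genes of a library. The glycolysis simulation therefore could not test how the list test behaves when genes of a list vary together.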

Results

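HUES8 cells were profiled by RNA sequencing (RNA) and ribosome profiling (Ribo) at definitive endoderm (DE, n = 2 per assay), early pancreatic progenitor (PP1, n = 2) and late pancreatic progenitor (PP2, n = 3) stages. The RNA libraries held 15107847 to 21009065 counts and the Ribo libraries 4710335 to 24186949. Principal components 1 and 2 held 61.1% and 22.2% of the variance in RNA and 58.6% and 19.4% in Ribo. Protein-coding genes took 87.3% to 90.3% of the counts in every RNA library. In Ribo they took 33.0% and 32.9% (DE), 27.1% and 29.9% (PP1), and 91.5%, 42.6% and 77.5% (PP2 replicates 1, 2 and 3). The mitochondrial ribosomal RNA MT-RNR2 took 49.97% and 49.2% of Ribo counts in DE, 60.8% and 57.7% in PP1, and 1.65%, 44.6% and 11.004% in PP2. Ribo PP2 replicates 1 and 3 thus differed in composition from the other 5 Ribo libraries. The 95% Wilson interval of each of these shares was at most 0.0446 percentage points to either side. P-values below measure the spread between libraries, which may be technical.

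**Figure D1:**
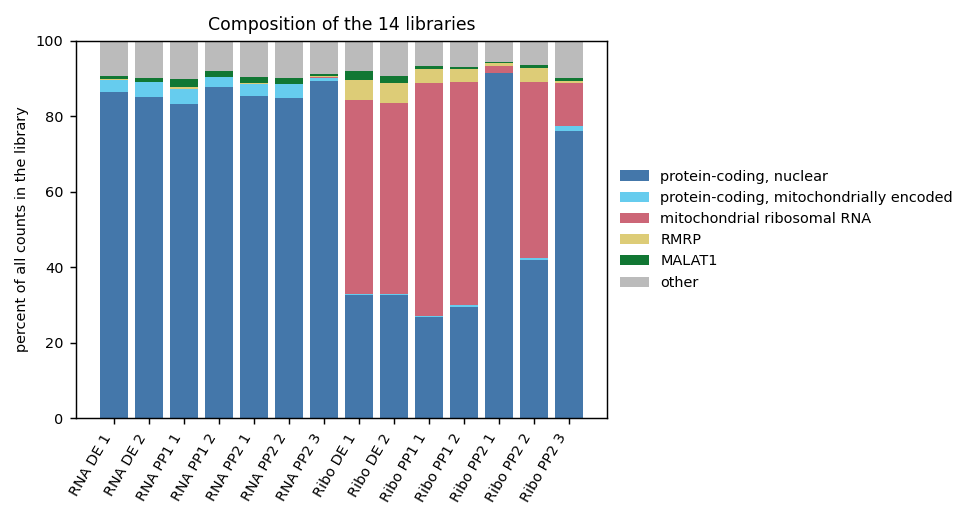
Share of all counts (percent) by gene class in each of the 14 libraries, 1 stacked bar per library. MT-RNR2 filled 60.8% of Ribo PP1 replicate 1 and 1.65% of Ribo PP2 replicate 1.

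RNA PP2 replicate 3 also stood apart from its group. Its mitochondrially encoded protein-coding genes took 0.950% of counts against 3.34% and 3.74% in replicates 1 and 2, and MALAT1 took 0.511% against 1.53% and 1.42%. The spread over counting noise (chi-square per degree of freedom) was 3.48 between replicates 1 and 2, and 141 and 152 when each was set against replicate 3. It was 5.22 between the RNA DE libraries and 17.05 between the RNA PP1 libraries. The Ribo DE and PP1 pairs gave 11.4 and 9.84, and the 3 Ribo PP2 pairs gave 857, 259 and 281. This measure can grow with depth, and the Ribo PP2 libraries were deeper than the other Ribo libraries. The Spearman correlation was 0.903 and 0.934 for the Ribo DE and PP1 pairs, and 0.885, 0.948 and 0.914 for the Ribo PP2 pairs. All libraries were kept.

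RNA at PP1 was compared with DE to ask which genes changed when endoderm was directed to a pancreatic fate. CER1, EOMES, SOX17 and MIXL1, which mark mesendoderm and definitive endoderm, fell, at log2 -12.05 ± 0.42, -7.48 ± 0.43, -5.38 ± 0.32 and -7.68 ± 0.44 (n = 2 against 2; adjusted p = 6.3e-06, 2.3e-05, 2.6e-05 and 2.2e-05). CER1 went from 4465 ± 136 CPM in DE to 1.04 ± 0.301 CPM in PP1. The plasma protein genes AFP and TTR had no RNA count in DE and rose at least 72339-fold and at least 10700-fold, and the pancreatic regulator PDX1 rose at least 645-fold (adjusted p = 9.2e-04). ONECUT2, CDX2, SOX9 and HES1 rose by log2 7.47 ± 0.29, 9.50 ± 0.68, 6.66 ± 0.85 and 6.45 ± 0.30. FN1, a matrix glycoprotein, rose by log2 4.84 ± 0.30 from 2058 ± 34.6 to 59074 ± 1446 CPM. CHAC1 and STC2, targets of the ATF4 stress pathway, rose by log2 4.30 ± 0.65 and 5.61 ± 0.76. The WNT target AXIN2 fell, at log2 -3.98 ± 0.27 and the retinoic acid target DHRS3 rose by log2 5.46 ± 0.26. By the edgeR quasi-likelihood test with BH adjustment, 3034 genes rose and 2945 fell, 5979 of 24603 tested. That count was 2995 without DE replicate 1, 2935 without DE replicate 2, 3262 without PP1 replicate 1, 3128 without PP1 replicate 2 and 11997 without PP2 replicate 3.

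Of the lists tested, 17 passed in this RNA comparison (2 with an estimated correlation). All 11 primitive streak and mesendoderm genes, among them GSC, EOMES and MIXL1, fell, and 11 fell adjusted over the list alone (median log2 -6.59, or -5.92 with bounds; adjusted p = 3.2e-31, and 0.0180 with an estimated correlation). Of 16 definitive endoderm genes, 1 rose, 11 fell and 4 did not pass (1 and 12 over the list alone), with SOX17 and CXCR4 among those that fell (median log2 -1.76, adjusted p = 7.2e-14, and 0.0195 with an estimated correlation). Without RNA PP2 replicate 3 neither of these lists passed with an estimated correlation (adjusted p = 0.0760 for each), and 0 lists did. Of 14 hepatic genes 13 rose and 1 did not pass (13 over the list alone), including APOB and APOA1 at log2 10.49 ± 0.50 and 4.56 ± 0.24. The hepatic median was log2 8.96 and its adjusted p was 1.8e-29, or adjusted p = 0.0899 with an estimated correlation. Of 19 pancreatic progenitor genes, such as PDX1, SOX9 and ONECUT2, 11 rose, 1 fell and 7 did not pass (11 and 2 over the list alone). Their median was log2 3.48, or 2.50 with bounds, and the adjusted p was 1.6e-10, or adjusted p = 0.116 with an estimated correlation. Of 20 integrated stress response genes 16 rose and 4 did not pass (17 over the list alone; median log2 2.77, adjusted p = 1.7e-09, and adjusted p = 0.164 with an estimated correlation). In the endoplasmic reticulum folding list HERPUD1 and SDF2L1 rose by log2 3.47 ± 0.25 and 2.26 ± 0.28, as did 9 of 20 genes in all (13 over the list alone; median log2 1.10, adjusted p = 6.3e-05, and adjusted p = 0.116 with an estimated correlation).

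**Figure D2:**
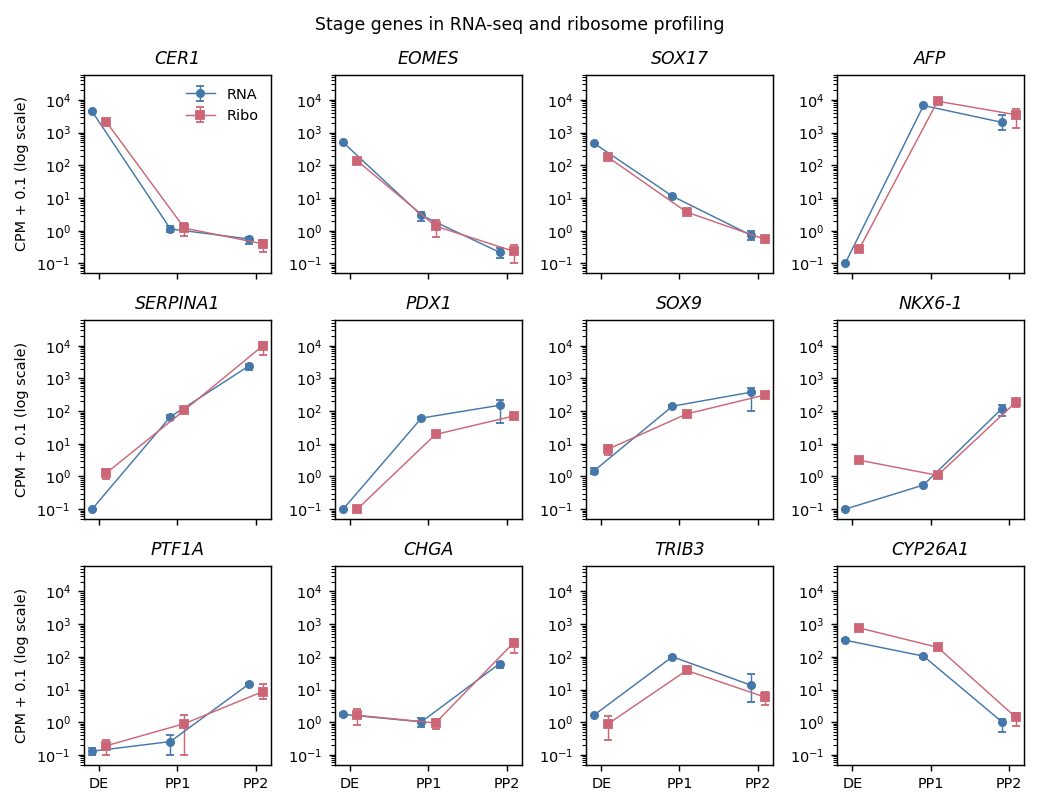
Mean CPM plus 0.1 (log axis) at DE, PP1 and PP2 for 12 genes, RNA as blue circles and Ribo as red squares, with bars from the lowest to the highest library. CER1 RNA went from 4465 CPM at DE to 0.460 CPM at PP2, and NKX6-1 RNA from 0.448 CPM at PP1 to 118 CPM at PP2.

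Ribo counts at PP1 were compared with DE to ask whether these changes were also present in Ribo. CER1, EOMES, SOX17 and CXCR4 fell, at log2 -10.92 ± 0.88, -6.75 ± 0.77, -5.59 ± 0.43 and -4.95 ± 0.53 (n = 2 against 2; adjusted p = 1.3e-04, 5.1e-04, 1.3e-04 and 3.2e-04). GSC had 1 count in PP1 and fell 1432-fold (counting interval 257 to 56583). FGB rose at least 2039-fold, and AFP, with 2 counts in DE, rose 51120-fold (14151 to 422126). HES1, ONECUT2 and SOX9 rose by log2 5.59 ± 0.54, 5.41 ± 0.56 and 3.58 ± 0.49, and the stress genes TRIB3 and CHAC1 by 5.56 ± 0.76 and 3.86 ± 0.56. In all 681 genes rose and 454 fell, 1135 of 15067 tested. The count was 496 without DE replicate 1, 473 without DE replicate 2, 450 without PP1 replicate 1, 424 without PP1 replicate 2 (304 higher, 120 lower) and 2228 without PP2 replicate 2.

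Among Ribo lists 15 passed (1 with an estimated correlation). Of 10 primitive streak genes, including EOMES and MIXL1, 7 fell and 3 did not pass (9 fell over the list alone; median log2 -7.43, or -5.81 with bounds; adjusted p = 1.8e-26, and 0.0215 with an estimated correlation). With Ribo PP2 replicates 1 and 3 left out its adjusted p was 0.121 with an estimated correlation, and 0 lists passed that way. Of 14 hepatic genes 11 rose and 3 did not pass (11 over the list alone; median log2 7.07, adjusted p = 7.1e-30, and adjusted p = 0.103 with an estimated correlation). Of 17 pancreatic progenitor genes, with SOX9 and ONECUT2 among them, 6 rose and 11 did not pass (6 rose and 1 fell over the list alone; median log2 0.75, adjusted p = 1.2e-06, and adjusted p = 0.0961 with an estimated correlation). Of 20 integrated stress response genes 11 rose and 9 did not pass (13 over the list alone; median log2 2.53, adjusted p = 6.1e-12, and adjusted p = 0.147 with an estimated correlation). Of 19 cytosolic aminoacyl-tRNA synthetase genes, which are partly under ATF4 control, 8 rose and 11 did not pass (13 over the list alone; median log2 1.37, adjusted p = 4.1e-08, and adjusted p = 0.391 with an estimated correlation).

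TE was compared between PP1 and DE to ask which genes changed in Ribo apart from RNA. The actin-binding MICAL2 and the vesicle protein gene SYTL5 fell in TE, at log2 -6.08 ± 0.51 and -5.04 ± 0.62 (n = 4 libraries per stage; adjusted p = 6.0e-05 and 2.3e-03). MICAL2 RNA went from 1.85 to 130.4 CPM while its Ribo value was 34.7 and 34.8 CPM, and SYTL5 RNA went from 0.707 to 217 CPM with Ribo at 8.94 and 78.4 CPM. SOX17, FN1 and APOA1 did not pass in TE, at log2 -0.16 ± 0.46, 0.05 ± 1.10 and 0.19 ± 0.64 (adjusted p = 0.946, 0.998 and 0.953). The pancreatic progenitor list, with 1 of 17 genes falling and 16 not passing (5 fell over the list alone), had a median of log2 -0.60, or -1.51 with genes of 0 to 3 counts at their bound or count ratio (adjusted p = 8.4e-04, and adjusted p = 0.912 with an estimated correlation). The hepatic list had 0 of 14 genes passing (3 fell over the list alone) and a median of log2 -2.55, or -1.55 with such genes at their bound or ratio (adjusted p = 9.4e-04, and adjusted p = 0.912 with an estimated correlation). Of its genes 7 had no count in a stage of at least 1 assay, so the size of this median depends on how such genes are treated. Of 76 cytosolic ribosomal protein genes 0 passed either way, at a median of log2 -0.51 (adjusted p = 8.4e-04, and adjusted p = 0.912 with an estimated correlation). Lists passing numbered 7 (0 with an estimated correlation). In all 10 genes rose and 28 fell in TE, 38 of 14152 tested. Left out singly, the libraries gave 7 and 9 (RNA DE replicates 1 and 2), 12 and 12 (RNA PP1 replicates 1 and 2), 25 and 24 (RNA PP2 replicates 1 and 2), 6 and 11 (Ribo PP1 replicates 1 and 2), and 62 and 132 (Ribo PP2 replicates 1 and 2). Without Ribo PP2 replicate 1, 29 were higher and 33 lower, and without replicate 2, 48 and 84. Limma voom gave 205 higher and 216 lower, and DESeq2 86 and 135, so the size of the lean to lower TE depended on the run.

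RNA at PP2 was compared with PP1 to ask what changed as progenitors matured. NKX6-1 and PTF1A, regulators of late pancreatic progenitors, rose by log2 8.04 ± 0.50 and 6.32 ± 0.62 (n = 3 against 2; adjusted p = 2.4e-04 and 6.2e-04). The endocrine genes CHGA and SCG2 rose by log2 6.09 ± 0.37 and 5.15 ± 0.70. The sodium channel subunit SCNN1G rose at least 225-fold. PDX1 and SOX9 did not pass, at log2 1.30 ± 0.61 and 1.42 ± 0.61 (adjusted p = 0.187 and 0.145). PDX1 spanned 42.1 to 212 CPM and SOX9 100.4 to 521 CPM among the PP2 libraries. Each rose without PP2 replicate 3 (log2 1.75 and 1.88; adjusted p = 3.9e-11 and 1.3e-11), as each did with limma voom (adjusted p = 2.1e-05 and 1.4e-05) or without a low-count filter (6.8e-06 and 6.7e-07), and SOX9 also with DESeq2 (0.0430). CYP26A1 and CYP26B1, which degrade retinoic acid, fell, at log2 -6.80 ± 0.38 and -4.32 ± 0.48, and the stress gene NUPR1 fell, at log2 -6.94 ± 0.44. HERPUD1, SDF2L1 and the glucose transporter gene SLC2A3 fell, at log2 -2.54 ± 0.21, -2.96 ± 0.24 and -3.38 ± 0.43. In all 1918 genes rose and 2615 fell, 4533 of 24603. The count was 1210 without PP1 replicate 1 (365 higher, 845 lower), 1376 without PP1 replicate 2 and 9984 without PP2 replicate 3. Of the genes that passed 42.3% rose, against 52.8% (2143 rose, 1913 fell) when only protein-coding genes were tested and counted in the library sizes, with a median shift of log2 0.10 in the genes tested in each run.

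Among RNA lists 11 passed (0 with an estimated correlation). Of 20 integrated stress response genes, including NUPR1 and CEBPB, 13 fell and 7 did not pass (19 fell over the list alone; median log2 -1.80, adjusted p = 1.4e-13, and adjusted p = 0.234 with an estimated correlation). Of 20 endoplasmic reticulum folding genes, such as HERPUD1 and SDF2L1, 14 fell and 6 did not pass (16 over the list alone; median log2 -1.55, adjusted p = 8.8e-12, and adjusted p = 0.0758 with an estimated correlation). Of 18 endocrine genes, with CHGA and SCG2 among those rising, 7 rose, 3 fell and 8 did not pass (11 and 3 over the list alone). The endocrine median was log2 1.70, or 1.76 with bounds (adjusted p = 6.3e-04, and adjusted p = 0.155 with an estimated correlation). Of 22 extracellular matrix genes 1 rose, 10 fell and 11 did not pass (1 and 11 over the list alone; median log2 -0.79, adjusted p = 0.00162, and adjusted p = 0.391 with an estimated correlation). Of 29 replication-dependent histone genes 2 rose and 27 did not pass (0 over the list alone; median log2 1.34, adjusted p = 1.2e-04, and adjusted p = 0.511 with an estimated correlation). The histone median was log2 0.52 without PP2 replicate 3. The pancreatic progenitor list did not pass with all libraries, with 6 of 19 genes rising and 3 falling (6 and 4 over the list alone; median log2 0.24, adjusted p = 0.0590). It passed without PP2 replicate 3 (median log2 0.62, adjusted p = 1.8e-06), but not when a correlation was also estimated (adjusted p = 0.119 with an estimated correlation).

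Ribo was compared between PP2 and PP1 to ask whether the same genes changed in that assay. NKX6-1 and CHGA rose by log2 7.57 ± 0.56 and 8.33 ± 0.82 (n = 3 against 2; adjusted p = 2.4e-04 and 1.0e-03), and SCNN1G rose at least 98.3-fold. PDX1 and SOX9 rose by log2 1.88 ± 0.35 and 1.93 ± 0.43 (adjusted p = 0.0174 and 0.0287). The PDX1 call was lost without PP1 replicate 1, PP1 replicate 2 or PP2 replicate 3 (adjusted p = 0.195, 0.202 and 0.0503). The SOX9 call was lost without DE replicate 1, DE replicate 2, PP1 replicate 1, PP1 replicate 2 or PP2 replicate 3 (adjusted p = 0.0515, 0.0505, 0.313, 0.249 and 0.0619). CYP26A1 fell, at log2 -7.17 ± 0.53. In all 325 genes rose and 430 fell, 755 of 15067. The count was 58 without PP1 replicate 1 (19 higher, 39 lower), 93 without PP1 replicate 2 (24 higher, 69 lower), 3474 without PP2 replicate 2 and 197 without PP2 replicate 3.

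Among Ribo lists 17 passed (0 with an estimated correlation). Of 17 pancreatic progenitor genes, with NKX6-1 among them, 4 rose, 2 fell and 11 did not pass (8 and 2 over the list alone; median log2 1.43, adjusted p = 5.2e-04, and adjusted p = 0.194 with an estimated correlation). Of 16 endocrine genes, including CHGA, 5 rose and 11 did not pass (6 rose and 1 fell over the list alone). The endocrine median was log2 2.17, or 2.05 with bounds (adjusted p = 6.1e-05, and adjusted p = 0.194 with an estimated correlation). Of 20 integrated stress response genes 6 fell and 14 did not pass (9 over the list alone; median log2 -1.03, adjusted p = 2.5e-07, and adjusted p = 0.292 with an estimated correlation). The endoplasmic reticulum folding list did not pass (2 of 20 fell, 3 over the list alone; median log2 -0.02, adjusted p = 0.567), but passed with PP2 replicates 1 and 3 left out (median log2 -0.63, adjusted p = 2.0e-06, and adjusted p = 0.267 with an estimated correlation). That run held 1 Ribo PP2 library, which was assumed to vary like the other groups. The extracellular matrix list, where 1 of 22 genes rose (3 over the list alone), had a median of log2 0.86 (adjusted p = 0.00451, and adjusted p = 0.802 with an estimated correlation). With PP2 replicates 1 and 3 left out it passed in the opposite direction, at -0.37 (adjusted p = 0.0471, and adjusted p = 0.442 with an estimated correlation). The mesoderm and mesenchyme list had a median of log2 -0.59, while the camera test ranked it upward without passing (adjusted p = 0.818). With PP2 replicates 1 and 3 left out its median was log2 -0.91, from the 1 remaining Ribo PP2 library.

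TE was compared between PP2 and PP1 in the same way. The chaperone genes PDIA4, HYOU1 and CALR did not pass singly, at log2 1.61 ± 0.48, 1.61 ± 0.49 and 1.66 ± 0.59 (n = 6 against 4 libraries; adjusted p = 0.238, 0.258 and 0.314). Each of the 3 rose in 4 other runs, namely without Ribo PP2 replicate 2 (adjusted p = 0.00883, 0.00551 and 0.0161), with DESeq2 (0.0288, 0.0332 and 0.0238), with limma voom (2.8e-04, 1.7e-04 and 2.0e-04) and without a low-count filter (0.0223, 0.0227 and 0.0139). The run without Ribo PP2 replicate 2 kept only replicates 1 and 3, whose composition differed. The DESeq2, limma voom and unfiltered runs also held these replicates, beside replicate 2. Rises in any of the 4 runs therefore cannot be told apart from composition. As a list, endoplasmic reticulum folding genes were higher in TE, with 0 of 20 passing singly (8 rose over the list alone; median log2 1.14, adjusted p = 4.5e-11, and adjusted p = 0.814 with an estimated correlation). The hormone gene CHGA stood at log2 2.09 ± 0.87 in TE (adjusted p = 0.407). The extracellular matrix list, with COL4A2 at log2 1.85 ± 0.65 (adjusted p = 0.00551 without Ribo PP2 replicate 2) and FN1 at 1.72 ± 1.02, had 0 of 22 passing singly (9 rose over the list alone; median log2 1.38, adjusted p = 4.5e-11, and adjusted p = 0.814 with an estimated correlation). Nuclear or structural noncoding RNAs had 0 of 13 passing either way and a median of log2 -0.79 (adjusted p = 0.00488, and adjusted p = 0.814 with an estimated correlation). Lists passing numbered 3 (0 with an estimated correlation). With Ribo PP2 replicates 1 and 3 left out, which leaves 1 Ribo PP2 library, assumed to vary like the other groups, the folding median was log2 0.72 (adjusted p = 0.00136, and adjusted p = 0.481 with an estimated correlation). The matrix median was then log2 0.35 (adjusted p = 0.111) and the noncoding median -0.37 (adjusted p = 0.552), and neither passed. In all 0 genes rose and 11 fell in TE among 14152, where 1486 had an unadjusted p under 0.05. The DESeq2 Wald test called 243 (71 higher, 172 lower) and limma voom 1856 (1006 higher, 850 lower), so the direction of the split depended on the tool. Left out singly, the libraries gave 2 and 2 (RNA DE replicates 1 and 2), 1 and 0 (RNA PP1 replicates 1 and 2), 2, 3 and 3 (RNA PP2 replicates 1, 2 and 3), 4 and 4 (Ribo DE replicates 1 and 2), 4 and 2 (Ribo PP1 replicates 1 and 2), and 2, 1110 and 6 (Ribo PP2 replicates 1, 2 and 3). Of the 1110 genes 365 were higher and 745 lower.

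**Figure D3:**
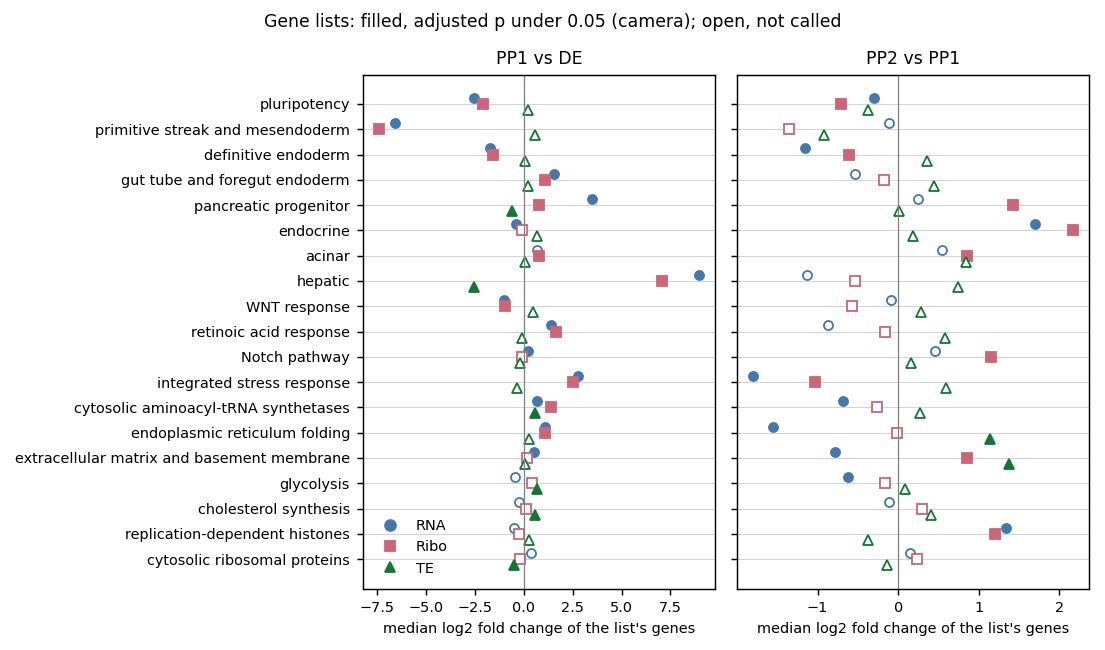
Median log2 fold change of the members of 19 gene lists for PP1 against DE and PP2 against PP1, as circles (RNA), squares (Ribo) and triangles (TE), filled where the camera adjusted p was under 0.05. Endoplasmic reticulum folding genes had a median of log2 -1.55 in RNA, -0.02 in Ribo and 1.14 in TE for PP2 against PP1.

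RNA at PP2 was compared with DE to measure the whole course. CER1, SOX17 and TDGF1 fell, at log2 -13.22 ± 0.36, -9.50 ± 0.33 and -11.26 ± 0.51 (n = 3 against 2; adjusted p = 1.8e-06, 2.8e-06 and 4.9e-06). SERPINA1, AFP, PDX1 and NKX6-1 had no RNA count in DE and rose at least 25060-fold, 22612-fold, 1558-fold and 1240-fold. SOX9, HES1 and the Notch ligand gene JAG1 rose by log2 8.08 ± 0.89, 6.53 ± 0.29 and 5.61 ± 0.28, while SLC2A3 fell, at log2 -6.15 ± 0.48. Of 16 definitive endoderm genes 13 fell and 3 did not pass (13 over the list alone; median log2 -3.60, adjusted p = 1.5e-24, and 0.00800 with an estimated correlation). Of 19 pancreatic progenitor genes 13 rose and 6 did not pass (13 over the list alone; median log2 4.37, adjusted p = 1.9e-13, and adjusted p = 0.117 with an estimated correlation). Without PP2 replicate 3 the estimated correlation gave adjusted p = 0.0529 for the definitive endoderm list and 0.0432 for the pancreatic progenitor list, the 1 list that then passed. All 14 hepatic genes rose (14 over the list alone; median log2 8.02, or 7.54 with bounds; adjusted p = 2.4e-21, and adjusted p = 0.117 with an estimated correlation). Lists passing numbered 11 (2 with an estimated correlation). In all 4034 genes rose and 4206 fell, 8240 of 24603. The count was 4481 without DE replicate 1, 4216 without DE replicate 2 and 12649 without PP2 replicate 3.

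In Ribo over the same course CER1, EOMES and SOX17 fell, at log2 -12.68 ± 0.76, -10.64 ± 0.77 and -8.49 ± 0.41 (n = 3 against 2; adjusted p = 7.4e-06, 1.5e-05 and 2.5e-06). SPINK1, which encodes a trypsin inhibitor, and PDX1 rose at least 8940-fold and at least 285-fold. SERPINA1, JAG1, NKX6-1 and SOX9 rose by log2 13.04 ± 1.33, 8.21 ± 0.74, 5.95 ± 0.48 and 5.52 ± 0.52. Of 17 pancreatic progenitor genes 11 rose and 6 did not pass (11 over the list alone; median log2 3.41, adjusted p = 1.1e-10, and 0.0383 with an estimated correlation). Of 16 definitive endoderm genes 11 fell and 5 did not pass (12 over the list alone; median log2 -2.45, adjusted p = 7.2e-18, and 0.0383 with an estimated correlation). With PP2 replicates 1 and 3 left out, which leaves 1 Ribo PP2 library, the estimated correlation gave adjusted p = 0.109 for each of these lists, and 0 lists passed. Lists passing numbered 21 (4 with an estimated correlation). In all 1974 genes rose and 2179 fell, 4153 of 15067. The count was 1810 without DE replicate 1, 1788 without DE replicate 2, 6837 without PP2 replicate 2 and 2133 without PP2 replicate 3.

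In TE over the same course MICAL2, SYTL5, LINC01355 and MEIS2 fell, at log2 -6.01 ± 0.47, -5.60 ± 0.58, -6.59 ± 0.59 and -2.31 ± 0.35 (n = 6 against 4 libraries; adjusted p = 2.3e-05, 1.4e-04, 5.4e-05 and 3.2e-03). SOX17 and CER1 did not pass, at log2 0.87 ± 0.46 and 0.38 ± 0.67 (adjusted p = 0.236 and 0.746). Of 20 endoplasmic reticulum folding genes 4 rose and 16 did not pass (9 rose over the list alone; median log2 1.25, adjusted p = 2.0e-05, and adjusted p = 0.667 with an estimated correlation). Of 22 cholesterol synthesis genes 3 rose and 19 did not pass (8 over the list alone; median log2 0.97, adjusted p = 5.0e-04, and adjusted p = 0.667 with an estimated correlation). Of 22 extracellular matrix genes 1 rose and 1 fell (13 and 1 over the list alone; median log2 1.52, adjusted p = 3.3e-04, and adjusted p = 0.905 with an estimated correlation). With Ribo PP2 replicates 1 and 3 left out 1 Ribo PP2 library remained, which was assumed to vary like the other groups. The folding median was then log2 0.60 (adjusted p = 0.00543, and adjusted p = 0.446 with an estimated correlation) and the matrix median 0.57 (adjusted p = 0.780). Lists passing numbered 10, 6 higher and 4 lower (0 with an estimated correlation). The lower ones were pancreatic progenitor (median log2 -1.05) and cytosolic ribosomal proteins (-0.67). With genes of 0 to 3 counts at their bound or count ratio the pancreatic progenitor median was log2 -1.86, which is not a bound and does not make the fall firmer. The lower lists also held endoderm and pancreas lncRNAs (-1.74) and nuclear or structural noncoding RNAs (-1.90). With Ribo PP2 replicates 1 and 3 left out the fitted medians of these lists were log2 -0.46, -0.57, -0.98 and -1.12. NKX6-1 also fell in TE (adjusted p = 2.7e-03). It had no RNA count in DE, so its fitted log2 of -7.59 ± 1.08 depends on how such genes are treated. That value cannot be read as a measured size. In all 284 genes rose and 520 fell, 804 of 14152. Left out singly, the libraries gave 64 and 52 (RNA DE replicates 1 and 2), 377 and 372 (RNA PP1 replicates 1 and 2), 341 and 360 (RNA PP2 replicates 1 and 2), and 3704 and 336 (Ribo PP2 replicates 2 and 3). The split was 476 higher and 525 lower without RNA PP2 replicate 3, 2080 and 2059 with limma voom, and 28 and 176 with glmTreat at 2-fold. It was 14 and 50 without RNA DE replicate 1, 9 and 43 without RNA DE replicate 2, and 94 and 278 without RNA PP1 replicate 2.

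Fold changes in RNA and Ribo were then set side by side over the 14152 genes tested in each. The Pearson correlation was 0.716 for PP1 against DE, 0.571 for PP2 against PP1 and 0.701 for PP2 against DE, and the Spearman correlation was 0.623, 0.538 and 0.553. Of genes passing in each assay, such as CER1 and SOX17 falling and HES1 rising, 978 of 980, 486 of 489 and 2285 of 2367 changed in the same direction. For PP2 against DE 1076 rose and 1209 fell in each assay, against 358 and 360 for lists drawn independently. Genes with TE against the RNA change numbered 30, 5 and 355, and those with TE along it 3, 1 and 94. In 20 simulations without a TE change the highest count of opposite genes was 1, 0 and 1, and the mean Pearson correlation was 0.861, 0.758 and 0.911.

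**Figure D4:**
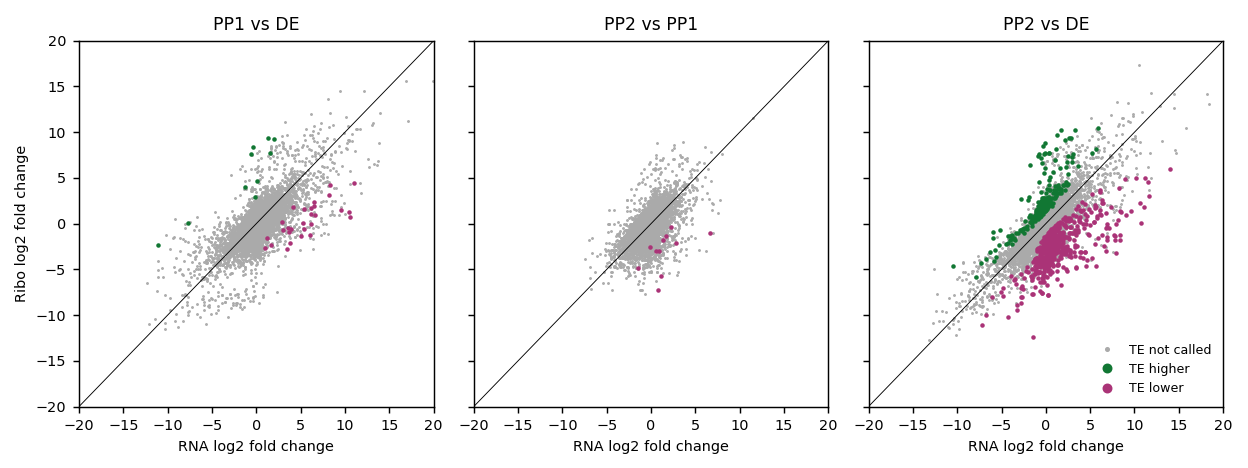
Fitted log2 fold change in RNA (x) and Ribo (y), 1 point per gene, for 3 stage comparisons, with genes that passed in TE in green (higher) or purple (lower) and a line of equality; folds of genes with 0 counts in a group depend on the prior count. The Pearson correlation for PP2 against PP1 was 0.571.

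The Ribo to RNA ratio within each stage was compared between lists, as the median over members of the difference of stage means. The sign ± gives the standard deviation over replicate numbers, with each Ribo library set against the RNA library of its number. These numbers are not known to mark pairs. Its median over all genes was log2 -0.07 at DE, -0.07 at PP1 and -0.05 at PP2. Cytosolic ribosomal protein genes, whose messages carry a 5' terminal oligopyrimidine tract, stood at log2 -1.04 ± 0.02, -1.57 ± 0.13 and -1.65 ± 0.48. The list of other genes with such a tract and elongation factors went the opposite way, at log2 -1.64 ± 0.07, -1.31 ± 0.11 and -1.14 ± 0.47. Endoplasmic reticulum folding genes such as HSPA5 and PDIA4 stood at log2 0.18 ± 0.06, 0.36 ± 0.10 and 1.84 ± 0.50, and extracellular matrix genes such as FN1 at -0.27 ± 0.10, -0.38 ± 0.04 and 1.07 ± 1.07. Nuclear or structural noncoding RNAs such as MALAT1 stood at log2 1.43 ± 0.11, 0.95 ± 0.10 and -0.61 ± 1.40. At DE and PP1 this noncoding list stood above the median of all genes, so Ribo counts need not all be ribosome-bound RNA. Ratios between assays depend on library composition, and they are not absolute translation rates.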

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

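Chosen after the data were seen were the alternatives with protein-coding genes only, RNA thinned to the Ribo protein-coding depth, Ribo thinned to the smallest protein-coding total, Ribo PP2 replicates 1 and 3 left out together, genes differing over 4-fold among the RNA PP2 libraries left out, lists without RNA PP2 replicate 3, the estimated correlation with these libraries left out, and the adjusted library scaling for list medians. Counts below are genes called, in the order PP1 against DE, PP2 against PP1 and PP2 against DE unless stated. Where the count moved, the cause was not tested. Where a library left out leaves 1 library in a group, that library was assumed to vary like the other groups.

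Limma voom called more genes than edgeR in every comparison, with 10952, 9600 and 12995 in RNA, 3048, 4175 and 6901 in Ribo, and 421, 1856 and 4139 in TE. The DESeq2 Wald test gave 1597 in Ribo for PP2 against PP1 and 221, 243 and 2069 in TE, with 162, 90 and 784 genes with TE against the RNA change. With glmTreat at 2-fold the counts were 2977, 1098 and 3839 in RNA, 548, 186 and 1923 in Ribo, and 18, 1 and 204 in TE. A fit of only the stages compared called 11211 genes in RNA and 3149 in Ribo for PP1 against DE.

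Without a low-count filter Ribo gave 1772 for PP2 against PP1 and TE gave 310, 615 and 3184. With the filter at a mean of 50 counts Ribo gave 2477 for PP2 against DE and TE gave 22, 5 and 234, the Pearson correlation of RNA and Ribo changes was 0.818, 0.718 and 0.786, and genes with TE against RNA numbered 19, 1 and 122. Leaving mitochondrially encoded and noncoding list genes out of the scaling gave 17 in TE for PP2 against PP1 and shifted the median TE change of PP2 against DE by log2 0.11. The filters moved the median of all genes in Ribo by log2 0.28 and 0.29 (no filter) and by -0.18 and -0.28 (mean of 50 counts) for PP2 against PP1 and PP2 against DE.

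RNA thinned to the Ribo depth gave 16 and 4 in TE for PP1 against DE and PP2 against PP1. RNA thinned to the Ribo protein-coding depth gave 3049, 2402 and 4715 in RNA and 14, 0 and 325 in TE. Ribo thinned to the smallest protein-coding total gave 61 in TE for PP1 against DE and 21 for PP2 against PP1. Without genes differing over 4-fold among the RNA PP2 libraries TE gave 23 for PP2 against PP1.

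With Ribo PP2 replicates 1 and 3 left out together, which leaves 1 Ribo PP2 library, Ribo gave 3005 for PP1 against DE and 2410 for PP2 against DE, and TE gave 185, 0 and 191. Lists called were 13 in Ribo for PP2 against DE and 6 in TE for PP2 against PP1, the Pearson correlation for PP2 against PP1 was 0.519, and genes with TE against RNA numbered 123, 0 and 132. Among lists that had passed with all libraries, medians that changed sign were, in Ribo PP2 against PP1, log2 -0.29 for nuclear-encoded oxidative phosphorylation and -0.37 for extracellular matrix. The mesoderm and mesenchyme median there went from log2 -0.59 to -0.91, where the test with all libraries had ranked it upward without passing. In Ribo PP2 against DE the mesoderm and mesenchyme list had also passed, and its median became log2 -0.24. In TE PP2 against PP1 medians of lists that had not passed changed sign too. Among them the hepatic and mesoderm medians became log2 -0.73 and -0.94. The WNT response and neural medians went from log2 0.28 to -0.38 and from -0.64 to 0.41. Without RNA PP2 replicate 3 the cytosolic ribosomal protein median of RNA PP2 against PP1 became log2 -0.28 (adjusted p = 0.00885) and the histone median of TE PP2 against PP1 became 0.49 (adjusted p = 0.0334), calls where the lists had not passed, and 8 TE lists were called for PP2 against PP1. SCN9A in TE PP2 against DE (log2 -6.19 ± 1.39 with all libraries) ranged from log2 -8.12 without RNA DE replicate 2 to 1.17 without Ribo DE replicate 2.

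Camera with an estimated correlation called 2, 0 and 2 lists in RNA, 1, 0 and 4 in Ribo, and 0, 0 and 0 in TE. With libraries also left out, an estimated correlation called 0, 0 and 1 lists in RNA (without RNA PP2 replicate 3), 0, 0 and 0 in Ribo (without Ribo PP2 replicates 1 and 3) and 0, 0 and 0 in TE either way. Fry called 19 lists in RNA and 11 in Ribo for PP2 against PP1, and 0, 0 and 0 in TE. With DESeq2 size factors the Ribo to RNA ratio at DE, PP1 and PP2 had a median of log2 -1.09, -1.12 and -1.08 over all genes, -2.10, -2.68 and -2.69 for cytosolic ribosomal proteins, and -0.88, -0.75 and 0.79 for endoplasmic reticulum folding. The noncoding list then stood at log2 0.38 at DE and -0.15 at PP1.

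Leaving out each library in turn, counts ranged from 2935 to 11997, 1210 to 9984 and 4216 to 12649 in RNA, from 424 to 2228, 58 to 3474 and 1788 to 6837 in Ribo, and from 6 to 132, 0 to 1110 and 52 to 3704 in TE. The Pearson correlation ranged from 0.581 to 0.732, 0.438 to 0.593 and 0.619 to 0.728. Genes with TE against RNA ranged from 6 to 95, 0 to 235 and 36 to 990. Of the genes named by rank, 16 of 16 in each RNA comparison kept their call in every such run, as did 15, 12 and 16 of 16 in Ribo. In TE 3 of 9, 0 of 3 and 6 of 16 did.

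Replicate numbers were also tried as a block. The block called 11711, 9758 and 12475 genes in RNA, 745, 201 and 1682 in Ribo, and 23, 3 and 455 in TE, and 19 RNA lists for PP2 against PP1, with 3 genes of TE against RNA in that comparison. The ribosomal protein median of RNA PP2 against PP1 became log2 -0.28 under the block (adjusted p = 1.4e-04), and PDX1 and SOX9 rose in RNA for PP2 against PP1 (log2 1.75 and 1.88; adjusted p = 7.6e-11 and 1.0e-11). Only PP2 had a replicate 3, so in the RNA fit the block gave RNA PP2 replicate 3 a term of its own. For RNA the block is therefore not separate from the run without that library, which gave the same log2 1.75 and 1.88. A block in which each culture was shared by RNA and Ribo gave 21, 2 and 301 in TE. Correlations of residuals between RNA and Ribo libraries of the same number ran from -0.134 to 0.102, and those between stages of 1 assay from -0.234 to 0.167, with 1 of 7 and 1 of 12 pairs over 0.1. In groups of 2 libraries the deviations mirror each other, so these pairs were not independent and could not show that pairing was absent. The labels did not say that the numbers mark pairs, and they were not used as pairs.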

Other observations

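The tests of counting noise, of nearness to PP1 and of hepatic and mitochondrial genes were chosen after results were seen, and the other tests below were chosen before they were run.

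Imprinted genes were followed because several of them mark growth in fetal liver and pancreas. H19, a maternally expressed noncoding RNA, had no RNA count in DE and rose at least 1953-fold by PP2, to 185 ± 35.4 CPM, with 2.30 CPM in Ribo. DLK1, a paternally expressed Notch-related gene, had 1476 ± 889 CPM in RNA and 9111 ± 3685 CPM in Ribo at PP2. Its rise over PP1 of log2 3.49 ± 0.62 in RNA passed (edgeR quasi-likelihood, BH adjusted p = 0.00733) but was lost without PP1 replicate 1 or 2 (adjusted p = 0.0930 and 0.0741). The Ribo rise of DLK1 of log2 5.93 ± 0.93 was lost in the same way (adjusted p = 0.180 and 0.139). Of 17 imprinted genes 6 rose and 2 fell in RNA for PP2 against PP1 (9 and 3 over the list alone; median log2 0.72, adjusted p = 0.0633). In Ribo 4 rose (4 rose and 1 fell over the list alone; median log2 0.72, adjusted p = 0.00276, and adjusted p = 0.194 with an estimated correlation).

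Among noncoding RNAs, LINC00458, a long noncoding RNA of pluripotent cells, had 136 ± 8.83 CPM in RNA at DE, 3.21 CPM at PP1 and 0.0938 CPM at PP2. The endoderm lncRNA LINC00261 had 291, 589 and 356 CPM in RNA at the 3 stages and 103, 96.8 and 54.1 CPM in Ribo. MIR302A, of a small RNA cluster active in pluripotent cells, had 8076 ± 669, 9034 ± 711 and 224 ± 293 CPM in Ribo, and 22.2, 0.137 and 0.0655 CPM in RNA. Its host transcript MIR302CHG had 471 ± 63.5 CPM in Ribo at DE and 0.963 CPM at PP1. Whether reads of small RNA genes came from the small RNA itself or from fragments was not tested, and read lengths were not used here.

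One pattern was TE changes called against the RNA change for PP2 against DE, in 355 genes, of which 246 rose in RNA and 109 fell. Simulated data without any TE change gave at most 1 such gene, so shared noise of the size simulated did not account for the 355. The simulated Pearson correlation of RNA and Ribo changes had a mean of 0.911, against 0.701 in the data. The simulation may therefore lack deviations of whole libraries, and these were not excluded. With Ribo PP2 replicates 1 and 3 left out, 132 genes were called against and 15 along the RNA change, but that run held 1 Ribo PP2 library, which was assumed to vary like the other groups, so the composition of these libraries stayed open. Reads in the Ribo DE libraries that do not follow the RNA remained open. Of the genes 69.3% rose in RNA and fell in TE, where at least 75% had been set for this explanation. That share depended on the run. It lay above 75% with the filter at a mean of 50 counts (93 of 122 genes) and without RNA PP2 replicate 1 (134 of 165). It lay below 75% with DESeq2 (456 of 784) and without RNA PP2 replicate 3 (292 of 531). For PP1 against DE, with the same Ribo DE libraries, 28 of 30 such genes rose in RNA. Genes with at most 3 RNA counts held 1.16% and 1.57% of protein-coding Ribo counts at DE and 0.420% and 0.337% at PP1. At PP2 they held 0.0103%, 0.120% and 0.0199%. Such counts may reflect carried-over or misassigned reads, or footprints on rare messages, and these cannot be told apart with gene counts.

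Another pattern was the distance of RNA PP2 replicate 3 from replicates 1 and 2. A sample closer to PP1 was excluded as the whole source, since its deviation had a slope of only 0.0479 on the difference of PP1 from PP2 (0.0730 and 0.0228 with either library as base) and it lay 187 units from PP1 on principal components 1 and 2, against 145 and 137 for replicates 1 and 2. A rank correlation of -0.160 with gene length over 14588 genes left a length bias open. Of 14 hepatic genes 12 were higher and 14.3% lower, among the latter the abundant SERPINA1 (by log2 -0.51), so a larger share of hepatocyte-like cells stayed open for these genes. All 13 mitochondrially encoded protein-coding genes were lower, with a median of log2 -2.70. The ribosomal RNA MT-RNR2 was higher, at 0.0608% of counts against 0.00252% and 0.00180% in replicates 1 and 2. The median lay past the limit set against hepatocyte-like cells, but that limit was set after the loss was seen. Mitochondrial transcripts of such cells were not measured here, so the result cannot exclude them as the source for these genes. Histone genes were higher by a median of log2 1.68 (28 of 29 genes), and the cause was not tested.

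The last pattern was higher TE of endoplasmic reticulum folding and extracellular matrix genes at PP2 against PP1. Without RNA PP2 replicate 3 the folding and matrix medians were log2 1.33 and 1.26, so that library was excluded as the only source. With Ribo PP2 replicates 1 and 3 left out they were log2 0.72 (adjusted p = 0.00136, and adjusted p = 0.481 with an estimated correlation) and 0.35 (adjusted p = 0.111), from 1 remaining Ribo PP2 library assumed to vary like the other groups, so the composition of these libraries stayed open for both lists. Denser ribosomes on secretory messages at PP2 may be another explanation, as a hypothesis that was not tested apart from it. With all libraries and an estimated correlation neither list passed, at adjusted p = 0.814.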
